A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

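Transcripts of Saccharomyces cerevisiae Y55 were measured in 12 cultures on single-colour NimbleGen arrays, with 1 array of Cy3-labelled cDNA per culture in the files. Per the labels, the cultures were 3 separate ones each of the wild type and of the UV-induced mutants fhf1, fhf2 and fhf3. They were grown in 200 mL of stirred rich medium with 20% maltose at 22 °C, from a start OD600 of 0.2 after a preculture of 72 h at 30 °C, and 40 mL were taken at day 2. The labels speak of hybridization in triplicate, while the files hold 1 value per gene and culture, which was taken as 1 replicate. Double-stranded cDNA was primed with oligo(dT) from purified mRNA, so the strand of a transcript could not be told. The arrays carried 8 probes of 60 nt per gene, printed 3 times, for 5777 genes, and the probes were designed on strain S288C. Members of gene families such as the MAL, HXT, PAU, COS and FLO genes may therefore share signal.

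The authors deposited 1 log2 value per gene and array, and the submitters' notes name limma without a version. How probes were summarized and background was corrected is not given in the sources used here. No normalization between arrays was visible in the deposited log2 values, whose array medians spanned 0.887 between 12.09 and 12.98. A second table deposited by the authors held log2 differences of each mutant from wild type, which equalled the differences of group means of the first table. It also held a test score, deposited by the authors and 0 for most genes, with nonzero scores only beyond a 2-fold difference. Its p-value columns, unadjusted and adjusted, are the authors' own as deposited, and the adjustment method is not given in the sources used here. The main analysis used the first table, in which 103 of 5872 entries had no values, and which left 5769 genes. A table of the reference genome assembly R64 served only for gene names and neighbours, and it matched 5763 of the locus tags and not the other 6. No genome build is named by the files, so no coordinates are given.

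The log2 values were quantile-normalized across the 12 arrays and fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0), with 1 mean per group. The fit had 8 residual degrees of freedom, 7.43 prior degrees of freedom and no covariate. Moderated tests were made for each mutant against wild type, each pair of mutants, the mean of the 3 mutants against wild type, and any difference among the strains (F test). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, two-sided. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision, and the median standard error of a mutant-minus-wild-type difference was 0.126.

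The design, the gene lists and the rule for naming genes were set before the data were examined. There were 48 gene lists of pathways and families, each with at least 3 measured genes, and limma's camera tested each against all other genes with a preset correlation between genes of 0.01. Adjusted p of lists are over the 48 lists of 1 comparison, and calls were repeated with a correlation estimated per list and with limma's fry. Fry asks whether the genes of a list move on balance 1 way and does not compare them with other genes. Named were, for each mutant against wild type, the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap with wild type. To these came up to 4 called genes of the largest change in each called list, the 5 largest differences each way between mutants, the 8 each way for the mean of the mutants and for genes changed in all 3, and 28 genes of sugar use, stress, flocculation and mating type whatever their values. From these, the examples in the text were picked after their values were seen, with preference for calls that held in other settings. Of the 321 named calls, 34 were lost on leaving out some array and 90 without normalization, and 225 held in both.

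Because the mutants share the wild-type arrays, overlaps were set beside the product of the 2 counts over the number of genes. They were also set beside 100 draws of unchanged groups, made by resampling whole-array residuals with random signs. The wild type of each draw was simulated in the same way, so the observed wild-type arrays were not kept. Steps were tested on simulated data of 5769 genes with 67, 67 and 66 genes changed 1.5, 2 and 4-fold. For fhf1 the fit recovered 86.6%, 100% and 100% of them with 6 false calls among 197. For fhf2 it recovered 76.1%, 100% and 98.5% with 15 false calls among 198, and for fhf3 77.6%, 100% and 100% with 11 among 196. The shifted list was called in each (adjusted p = 8.81e-18, 1.43e-22 and 1.24e-16), and for fhf1 1 list that had not been shifted was called too. The simulated genes varied independently, so these data cannot test camera's preset correlation. Few genes were changed, so they also cannot test normalization where many genes change, as in fhf3 with 47.9% of genes called.

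The alternatives were cyclic loess, median centring, a replicate block, a fit of only the compared groups, an intensity trend or robust variance, array weights, a filter of the lowest 25% of genes, a log2 limit of 1, treat at a log2 limit of 0.263, other list tests, and leaving out each array. Added after seeing the data were no normalization, treat at 2-fold without normalization, a correction for coding length and a filter of the highest 10% of genes. The authors' second table was used only for comparison.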

Results

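Transcript levels were measured on single-colour arrays in 12 separate cultures of Saccharomyces cerevisiae Y55, a laboratory strain whose genotype is given as MAT-alpha MAL1 SUC1. There were 4 groups of 3 cultures, which were the wild type and its UV-induced mutants fhf1, fhf2 and fhf3, all 3 of them described as fast-fermenting on maltose. Cells were taken at day 2 from stirred semi-aerobic fermentations of 20% maltose at 22 °C. Values were available for 5769 genes, and the medians of the deposited log2 signals lay between 12.09 and 12.98 on the 12 arrays. Differences below are log2 differences with their standard error (SE), each from 3 cultures against 3, and the median SE of a mutant-minus-wild-type difference was 0.126. The number of arrays limits the precision, and differences among the strongest signals may be compressed, since 18 of 24 genes of glycolysis and ethanol formation had a mean level above the 90th percentile of all genes (13.83).

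The arrays of fhf3 were the ones farthest from those of the other strains. Across genes, which are not independent replicates, the mean correlation of array pairs was 0.872 between fhf3 and wild type, 0.950 between fhf1 and wild type, and 0.965 between fhf2 and wild type. The mutants fhf1 and fhf2 correlated at 0.976 with each other, and arrays of 1 strain correlated at 0.977 (fhf1), 0.990 (fhf2), 0.985 (fhf3) and 0.977 (wild type). The first principal component held 60.7% of the variance and the next held 15.4%. By limma's F test, 3147 genes differed among the 4 strains at an adjusted p under 0.05.

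The genes closest to the selected trait are those that take up and cleave maltose, and no difference from wild type was detected in most of them. The maltose permease MAL31 (YBR298C) had a mean level of 14.81 ± 0.0255 (SD, n = 3) in wild type and of 14.87 ± 0.144, 14.72 ± 0.129 and 14.67 ± 0.109 in fhf1, fhf2 and fhf3. Its differences from wild type were 0.06, -0.09 and -0.13 (SE 0.109, adjusted p = 0.741, 0.722 and 0.326). The maltase MAL32 (YBR299W) differed by 0.16, 0.11 and 0.06 (SE 0.116, adjusted p = 0.371, 0.663 and 0.705), and MAL12 (YGR292W), a second maltase gene, by 0.10, -0.02 and -0.17 (adjusted p = 0.6, 0.963 and 0.209). MAL genes may share signal, so these values may not stand for separate loci. The level of MAL31 also lay above the 90th percentile of all genes (13.83), where differences may be compressed. The probes of MAL11 (YGR289C) and MAL13 (YGR288W), designed on the S288C genome, gave levels of 7.74 and 7.79 in wild type, near the lowest signals on the arrays, so these loci could not be assessed. The MAL activator gene MAL33 (YBR297W) rose in fhf3 by 0.58 ± 0.109 (adjusted p = 0.00043), a call that was lost without normalization between arrays (0.19), and did not pass in fhf1 (0.29, adjusted p = 0.0801) or fhf2 (0.23, adjusted p = 0.256). The isomaltase IMA1 (YGR287C) did not pass in any mutant (0.22, -0.04 and 0.30, adjusted p = 0.307, 0.913 and 0.0935). Of the 13 measured genes of maltose use, 1 rose in fhf1 and 1 in fhf3 (of these, the 1 in fhf3 when adjusted over the list alone). The median differences of that list were 0.12, 0.02 and -0.01, and limma's camera test gave adjusted p = 0.267, 0.877 and 0.909.

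Several genes of hexose transport and phosphorylation changed. HXT5 (YHR096C), a transporter of moderate affinity induced in slow growth, fell in all 3 mutants, with differences of -1.85, -1.60 and -2.71 (SE 0.114, adjusted p = 4.12e-08, 1.81e-07 and 4.79e-11). HXK2 (YGL253W), the main hexokinase of growth on glucose, fell in fhf1 (-1.56 ± 0.156, adjusted p = 6.13e-06) and fhf2 (-0.77, adjusted p = 0.00652) and rose in fhf3 (1.39, adjusted p = 3.14e-06). The low-affinity transporter HXT3 (YDR345C) fell in fhf1 (-1.55 ± 0.128, adjusted p = 8.69e-07) and fhf3 (-0.87, adjusted p = 5.01e-05). In fhf2 its fall of -0.50 had adjusted p = 0.0267, which became 0.0583 and 0.152 without fhf2 replicates 1 and 2, and 0.0556, 0.0528 and 0.0776 without wild-type replicates 1, 2 and 3. HXT4 rose in fhf3 (0.63 ± 0.146, adjusted p = 0.0024) and did not pass in fhf1 (-0.35, adjusted p = 0.125) or fhf2 (-0.27, adjusted p = 0.317). The differences of HXT1 (0.16, 0.14 and -0.09), HXT2 (0.04, 0.21 and -0.17), HXT6 (-0.21, -0.22 and -0.25), HXT7 (-0.03, 0.10 and -0.20) and HXK1 (0.07, 0.04 and -0.03) did not pass in fhf1, fhf2 or fhf3. Without normalization between arrays the calls of HXK2 in fhf2 (-0.68), HXT3 in fhf2 (-0.42) and HXT4 in fhf3 (0.14) were lost.

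The main genes of ethanol formation did not pass, while genes of glycerol formation and sucrose cleavage passed in some mutants. The pyruvate decarboxylase PDC1 differed by -0.09, 0.03 and 0.01 (adjusted p = 0.589, 0.916 and 0.921) and the alcohol dehydrogenase ADH1 by -0.08, -0.03 and -0.17 (adjusted p = 0.671, 0.911 and 0.199). Of the 24 genes of glycolysis and ethanol formation, 1 rose and 3 fell in fhf1, 2 fell in fhf2, and 4 rose and 1 fell in fhf3. The list medians were -0.02, 0.01 and 0.05 (adjusted p = 0.508, 0.56 and 0.686). The glycerol 3-phosphate dehydrogenase GPD1 (YDL022W) fell in fhf3 (-0.83 ± 0.108, adjusted p = 1.58e-05). In fhf1 GPD1 rose by 0.36 (adjusted p = 0.0346), a call lost without normalization (0.52) and without fhf1 replicate 1, 2 or 3 (adjusted p = 0.0769, 0.0671 and 0.0689) or wild-type replicate 2 or 3 (0.0526 and 0.136). The invertase SUC2 (YIL162W) rose in fhf3 (0.92 ± 0.121, adjusted p = 1.59e-05), and in fhf2 by 0.46 (adjusted p = 0.0315). The genotype names SUC1 and the probes were designed on S288C, so this signal may not stand for SUC2 alone. The fhf2 call was lost without fhf2 replicate 1 or 3 (adjusted p = 0.143 and 0.0999) or wild-type replicate 1 or 3 (0.0963 and 0.0642), and both SUC2 calls were lost without normalization (0.59 in fhf3 and 0.55 in fhf2). The ethanol-oxidizing ADH2 (YMR303C) passed in fhf3 at 0.34 ± 0.128 (adjusted p = 0.0396), but its difference was -0.13 without normalization. That call was also lost without fhf2 replicate 3 (0.0515), fhf3 replicate 1 or 2 (0.113 and 0.107) or wild-type replicate 2 or 3 (0.181 and 0.0532).

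**Figure D1:**
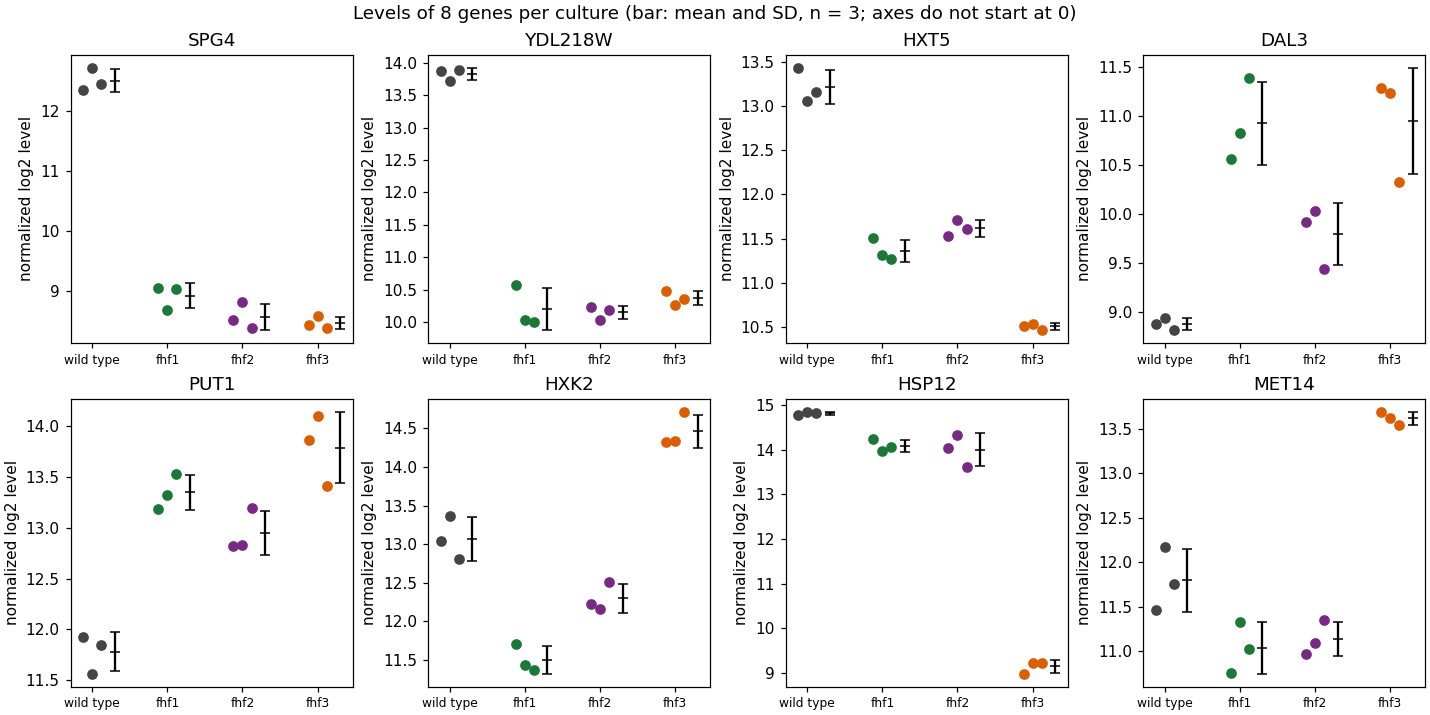
Quantile-normalized log2 levels of 8 genes in the 12 arrays, with 1 point per array and a bar at the mean and SD of each group (n = 3). SPG4 had mean levels of 8.93, 8.58 and 8.47 in fhf1, fhf2 and fhf3 against 12.50 in wild type, and HSP12 had a mean level of 9.14 in fhf3 against 14.82.

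The comparison of fhf1 with wild type asked which transcripts differed in a mutant described as fast-fermenting on maltose. Among its largest rises were genes that break down allantoin and proline, namely the ureidoglycolate lyase DAL3 (YIR032C; 2.05 ± 0.239, adjusted p = 2.71e-05) and the proline oxidase PUT1 (YLR142W; 1.57 ± 0.167, adjusted p = 1.16e-05). The thiamine-repressed pyruvate decarboxylase PDC5 (YLR134W) rose by 1.41 ± 0.136 (adjusted p = 3.92e-06), the mitochondrial nuclease DIN7 (YDR263C) by 1.41 ± 0.114 (adjusted p = 6.62e-07) and THI22 by 1.40 ± 0.119 (adjusted p = 1.07e-06). The largest falls were in the uncharacterized YDL218W (-3.63 ± 0.139, adjusted p = 1.26e-10) and in SPG4 (YMR107W; -3.58 ± 0.139, adjusted p = 1.26e-10), which is required in stationary phase at high temperature. SDH9 (YJL045W), a minor succinate dehydrogenase subunit, changed by -2.87 ± 0.201 (adjusted p = 1.33e-07), the aquaporin AQY1 (YPR192W) by -2.70 ± 0.216 (adjusted p = 6.01e-07) and the succinate-fumarate carrier SFC1 (YJR095W) by -2.25 ± 0.117 (adjusted p = 6.79e-09). In each of these 10 genes all 3 mutant arrays lay on 1 side of all 3 wild-type arrays, as the rule for naming required.

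In fhf1 the medians of ribosomal, cell division, gluconeogenic and peroxisomal genes were lower, by calls that were lost with an estimated correlation. Of 131 cytosolic ribosomal protein genes 86 fell, such as RPS22A (-1.68 ± 0.178) and RPS26B (-1.42 ± 0.215), and 45 did not pass (104 fell and 1 rose when adjusted over the list alone). Their median was -0.57 (adjusted p = 7e-34), with array medians of -0.89, -0.56 and -0.32 in fhf1 against -0.18, 0.23 and -0.05 in wild type. Of 79 ribosome biogenesis genes 26 fell, such as NSR1 (-1.14 ± 0.12), and 2 rose (34 and 2 when adjusted over the list alone), with a median of -0.30 (adjusted p = 1.17e-11). With an estimated correlation these became adjusted p = 0.379 and 0.137. Among genes of mitosis 12 of 35 fell, such as the cyclin CLB2 (-1.67 ± 0.289, adjusted p = 0.00113), and 1 rose (15 and 3 when adjusted over the list alone). Their median was -0.28 (adjusted p = 0.000191, and adjusted p = 0.445 with an estimated correlation). In the list of G1/S and DNA replication 11 of 51 fell, such as PCL1 (-1.66 ± 0.23) and MCD1 (-1.35 ± 0.212), and 3 rose (14 and 5 when adjusted over the list alone). Its median was -0.13 (adjusted p = 0.00482, and adjusted p = 0.493 with an estimated correlation). Among gluconeogenic and glyoxylate genes 6 of 24 fell, such as PCK1 (-1.40 ± 0.142), and 2 rose (10 and 2 when adjusted over the list alone), with a median of -0.20 (adjusted p = 0.0024, and adjusted p = 0.526 with an estimated correlation). The array medians of this list overlapped, with -0.018, -0.287 and -0.305 in fhf1 against 0.122, -0.204 and 0.087 in wild type. Of 27 peroxisomal genes 9 fell, such as POT1 (-1.54 ± 0.162), and 2 rose (12 and 3 when adjusted over the list alone), with a median of -0.28 (adjusted p = 0.000483, and adjusted p = 0.288 with an estimated correlation).

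Camera called 9 further lists in fhf1. Of 32 general stress genes 7 fell, such as ALD2 (-1.53 ± 0.135), with 10 when adjusted over the list alone and a median of -0.21 (adjusted p = 0.000483, and adjusted p = 0.201 with an estimated correlation). The stress gene HSP12 changed by -0.72 ± 0.151 (adjusted p = 0.00413). Translation factors and tRNA synthetases had a median of -0.16, with 5 of 45 lower (3 when adjusted over the list alone, adjusted p = 0.000483, and adjusted p = 0.379 with an estimated correlation). Sulphur assimilation genes had a median of -0.09, with 10 of 33 lower and 1 higher (11 and 1 when adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.474 with an estimated correlation). Histone genes had a median of -0.24, with 1 of 10 lower (adjusted p = 0.022, and adjusted p = 0.493 with an estimated correlation). Seripauperins rose, with 11 of 21 higher, such as PAU11 (0.85 ± 0.11), 13 when adjusted over the list alone, and a median of 0.48 (adjusted p = 1.78e-06, and adjusted p = 0.462 with an estimated correlation). Genes under nitrogen catabolite repression had a median of 0.25, with 9 of 32 higher and 1 lower (11 and 1 when adjusted over the list alone, adjusted p = 0.000207, and adjusted p = 0.379 with an estimated correlation). COS genes had a median of 0.29, with 3 of 11 higher, among them COS10 (1.28 ± 0.135), and 5 when adjusted over the list alone (adjusted p = 0.00114, and adjusted p = 0.201 with an estimated correlation). Ergosterol genes had a median of 0.20, with 6 of 30 higher (9 when adjusted over the list alone, adjusted p = 0.00159, and adjusted p = 0.137 with an estimated correlation). Iron regulon genes had a median of 0.21, with 6 of 32 higher and 1 lower (6 and 1 when adjusted over the list alone, adjusted p = 0.022, and adjusted p = 0.474 with an estimated correlation).

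Over all genes, limma called 446 higher and 514 lower in fhf1, of which 25 and 79 differed at least 2-fold. Of 48 lists camera called 15, of which 5 rose, and with an estimated correlation it called 0 (5 at an unadjusted p under 0.05, and 20 by limma's fry). Several of these list calls depended on single arrays. The call of histones was lost without fhf1 replicate 1 (-0.17, adjusted p = 0.193) or wild-type replicate 2 (-0.18, adjusted p = 0.133). That of the iron regulon was lost without the same arrays (0.12, adjusted p = 0.0919, and 0.09, adjusted p = 0.146). The sulphur call was lost without fhf1 replicate 3 (-0.08, adjusted p = 0.092), wild-type replicate 1 (-0.02, adjusted p = 0.0792) or wild-type replicate 3 (-0.14, adjusted p = 0.055). When the values were not normalized between arrays, 34 genes were higher and 120 lower, so the share of higher genes moved from 46.5% to 22.1%. The calls of general stress (adjusted p = 0.061), translation (0.136), sulphur (0.168), iron (0.0541) and histone genes (0.136) and of HSP12 were then lost. Their medians were -0.09, -0.12, -0.06, 0.18 and -0.20, the difference of HSP12 was -0.55, and the ergosterol median was 0.36.

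The comparison of fhf2 with wild type gave the fewest changed genes of the 3 mutants. Its largest rises included the methyltransferase EFM6 (YNL024C; 1.31 ± 0.15, adjusted p = 3.8e-05), the urea amidolyase DUR12 (YBR208C; 1.25 ± 0.115, adjusted p = 3.38e-06) and the proline oxidase PUT1 (1.17 ± 0.167, adjusted p = 0.000407). FUS2 (YMR232W), which acts in cell fusion during mating, rose by 0.99 ± 0.104 (adjusted p = 1.37e-05). SPG4 (-3.93 ± 0.139, adjusted p = 6.19e-11), YDL218W (-3.68 ± 0.139, adjusted p = 7.76e-11), the spore wall gene SPS100 (YHR139C; -3.19 ± 0.146, adjusted p = 8.39e-10) and AQY1 (-2.94 ± 0.216, adjusted p = 2.17e-07) fell most. The thiazole synthase THI4 (YGR144W) changed by -2.38 ± 0.11 (adjusted p = 8.39e-10) and the transporter HXT13 (YEL069C) by -1.65 ± 0.122 (adjusted p = 2.33e-07). The flocculin FLO11 (YIR019C) changed by -0.88 ± 0.131 (adjusted p = 0.00052) and HSP12 by -0.82 ± 0.151 (adjusted p = 0.00307), and both calls were lost without normalization between arrays (-0.73 and -0.66).

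By group, the medians of ribosomal, gluconeogenic and stress genes were lower in fhf2 and that of mitochondrial ribosome genes was higher, while most members did not pass. Of 131 cytosolic ribosomal protein genes 30 fell, such as RPS22A (-1.07 ± 0.178), and 101 did not pass (78 fell when adjusted over the list alone). Their median was -0.43 (adjusted p = 8.22e-27, and adjusted p = 0.338 with an estimated correlation). Of 79 ribosome biogenesis genes 11 fell (35 fell and 1 rose when adjusted over the list alone), with a median of -0.30 (adjusted p = 6.59e-15, and adjusted p = 0.0631 with an estimated correlation). Of 24 gluconeogenic and glyoxylate genes 10 fell, such as SFC1 (-1.73 ± 0.117) and PCK1 (-1.59 ± 0.142), and 1 rose (13 and 1 when adjusted over the list alone). Their median was -0.35 (adjusted p = 1.77e-07, and adjusted p = 0.321 with an estimated correlation). General stress genes had a median of -0.21, with 6 of 32 lower, such as ALD2 (-1.41 ± 0.135), and 10 when adjusted over the list alone (adjusted p = 3.49e-07, and adjusted p = 0.0631 with an estimated correlation). Mitochondrial ribosome genes had a median of 0.23, with 3 of 66 higher (3 when adjusted over the list alone, adjusted p = 3.49e-07, and adjusted p = 0.409 with an estimated correlation). All 3 gene calls, of MRP1 (0.56), MRPL17 (0.43) and MRPL7 (0.42), were lost without normalization (adjusted p = 0.512, 0.988 and 0.97), and the last 2 also on leaving out any of 5 arrays. The array medians of the mitochondrial ribosome list overlapped, with 0.17, 0.33 and 0.22 in fhf2 against -0.16, 0.21 and -0.03 in wild type. Seripauperins had a median of 0.42, with 7 of 21 higher, such as PAU23 (0.92 ± 0.154), 13 higher and 1 lower when adjusted over the list alone (adjusted p = 3.49e-07, and adjusted p = 0.338 with an estimated correlation). COS genes had a median of 0.31, with 4 of 11 higher (6 when adjusted over the list alone, adjusted p = 1.81e-05, and adjusted p = 0.0807 with an estimated correlation). Without fhf2 replicate 1 the limma calls of COS8, COS6 and COS5 were lost (adjusted p = 0.0658, 0.0742 and 0.0806). They were also lost without fhf2 replicate 3 (0.15, 0.0774 and 0.162) or wild-type replicate 2 (0.0645, 0.0529 and 0.0856). Leaving out certain other arrays ended these calls too, such as fhf2 replicate 2 for COS8 (0.0611) and COS5 (0.0799).

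In fhf2 camera called 7 further lists. Peroxisomal genes had a median of -0.21, with 4 of 27 lower, such as POT1 (-1.11 ± 0.162; 6 when adjusted over the list alone, adjusted p = 0.000115, and adjusted p = 0.23 with an estimated correlation). Sulphur assimilation genes had a median of -0.12, with 10 of 33 lower (12 when adjusted over the list alone, adjusted p = 0.00017, and adjusted p = 0.23 with an estimated correlation). Genes of mitosis had a median of -0.21, with 3 of 35 lower (6 when adjusted over the list alone, adjusted p = 0.00061, and adjusted p = 0.386 with an estimated correlation). Genes of RNA polymerases I and III had a median of -0.09, with 2 of 27 lower (4 when adjusted over the list alone, adjusted p = 0.0345, and adjusted p = 0.23 with an estimated correlation). Translation factors and tRNA synthetases had a median of -0.07 (adjusted p = 0.0345, and adjusted p = 0.398 with an estimated correlation). Genes under nitrogen catabolite repression had a median of 0.11, with 5 of 32 higher and 1 lower (8 and 2 when adjusted over the list alone, adjusted p = 0.0345, and adjusted p = 0.478 with an estimated correlation). Hexose transport genes had a median of -0.10, with 4 of 21 lower, such as HXT17 (-1.08 ± 0.111), and 1 higher (4 and 1 when adjusted over the list alone, adjusted p = 0.041, and adjusted p = 0.325 with an estimated correlation). The last 4 of these calls each ended on leaving out single arrays. For RNA polymerases these were fhf2 replicate 3 (-0.10, adjusted p = 0.0781) and wild-type replicate 2 (-0.06, adjusted p = 0.128). For nitrogen genes they were fhf2 replicate 1 (0.07, adjusted p = 0.0754) and wild-type replicate 2 (0.04, adjusted p = 0.145). For hexose transport they were fhf3 replicate 3 (-0.10, adjusted p = 0.0554) and wild-type replicates 1 (-0.07, adjusted p = 0.109) and 3 (-0.05, adjusted p = 0.0649). For translation they were fhf2 replicates 2 (0.106) and 3 (0.0813) and wild-type replicates 2 (0.128) and 3 (0.0576), and without normalization its median was 0.04 (adjusted p = 0.425).

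Over all genes, limma called 135 higher and 253 lower in fhf2, of which 5 and 49 differed at least 2-fold. The total of 388 became 246, 213 and 224 without fhf2 replicates 1, 2 and 3, and 225 without wild-type replicate 3. Of 48 lists camera called 14, of which 4 rose, and with an estimated correlation it called 0 (9 at an unadjusted p under 0.05, and 15 by fry). The unnormalized values gave 13 higher and 46 lower genes, so the share of higher genes moved from 34.8% to 22.0%, with a median of all genes of 0.10. The medians of hexose transport (-0.02), general stress (-0.09), RNA polymerase (-0.05), sulphur (-0.04) and peroxisomal genes (-0.12) were then nearer to 0, and that of nitrogen genes was 0.18.

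The comparison of fhf3 with wild type gave the most changed genes of the 3 mutants. The membrane stress protein gene HSP12 (YFL014W) changed by -5.67 ± 0.151 (adjusted p = 7.64e-13), from a level of 14.82 in wild type to 9.14. AQY1 changed by -5.55 ± 0.216 (adjusted p = 2.6e-11), SDH9 by -4.94 ± 0.201 (adjusted p = 3.9e-11), the mitochondrial protein gene FMP16 (YDR070C) by -4.63 ± 0.146 (adjusted p = 3.34e-12) and SPG4 by -4.04 ± 0.139 (adjusted p = 5.96e-12). The largest rises were in PRM7 (YDL039C; 3.35 ± 0.281, adjusted p = 1.26e-07), BSC1 (YDL037C; 3.15 ± 0.158, adjusted p = 2.78e-10) and YDL038C (2.81 ± 0.203, adjusted p = 2.19e-08). These lie next to each other, and in assembly R64 YDL038C is part of PRM7. The meiotic splicing gene MER1 (YNL210W) rose by 2.37 ± 0.124 (adjusted p = 4.34e-10), DAL3 by 2.07 ± 0.239 (adjusted p = 4.46e-06) and the ferric reductase FRE4 (YNR060W) by 2.06 ± 0.105 (adjusted p = 3.08e-10). The trehalose synthesis genes TPS1 (-0.65 ± 0.143, adjusted p = 0.00157) and TSL1 (-1.03 ± 0.11, adjusted p = 1.98e-06) and the chaperone HSP26 (-0.85 ± 0.114, adjusted p = 2.01e-05) fell in fhf3. In fhf1 and fhf2 TPS1 (0.03 and -0.12), TSL1 (0.07 and 0.08) and HSP26 (0.08 and 0.09) did not pass.

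Of the lists that fell in fhf3, 5 held their call with an estimated correlation. Of 32 general stress genes 27 fell, such as SIP18 (-4.17 ± 0.144) and DDR2 (-3.44 ± 0.148), and 2 rose (27 and 2 when adjusted over the list alone). The list median was -1.46 (adjusted p = 1.33e-16, and adjusted p = 0.00632 with an estimated correlation), and the array medians were -1.51, -1.50 and -1.44 in fhf3 against 0.05, -0.06 and 0.06 in wild type. Of 27 peroxisomal genes 21 fell, such as POT1 (-4.01 ± 0.162) and FOX2 (-3.10 ± 0.164), with 22 when adjusted over the list alone and a median of -0.93 (adjusted p = 9.03e-12, and adjusted p = 0.0184 with an estimated correlation). Of 19 tricarboxylic acid cycle genes 16 fell, such as ACO1 (-1.40 ± 0.0999) and SDH2 (-1.26 ± 0.0946), and 1 rose (16 and 1 when adjusted over the list alone). The median was -0.66 (adjusted p = 3.82e-06, and adjusted p = 0.0184 with an estimated correlation). Of 30 oxidative stress genes 16 fell, such as OYE3 (-2.55 ± 0.141), and 3 rose (16 and 3 when adjusted over the list alone), with a median of -0.28 (adjusted p = 4.46e-05, and adjusted p = 0.0249 with an estimated correlation). Of 30 genes of autophagy and vacuolar proteases 15 fell, such as ATG3 (-1.16 ± 0.11), and 3 rose, among them ATG5 (1.22 ± 0.137), with the same counts when adjusted over the list alone and a median of -0.34 (adjusted p = 0.00289, and adjusted p = 0.0366 with an estimated correlation).

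The other lists that fell in fhf3 lost their call with an estimated correlation. Of 40 genes of the respiratory chain and ATP synthase 35 fell, such as NDE2 (-3.76 ± 0.199) and INH1 (-1.96 ± 0.124), and 35 when adjusted over the list alone, with a median of -0.61 (adjusted p = 9.03e-12, and adjusted p = 0.0636 with an estimated correlation). Of 18 trehalose and glycogen genes 17 fell, such as GLG2 (-1.95 ± 0.115) and NTH2 (-1.51 ± 0.112), and 1 rose (17 and 1 when adjusted over the list alone). The median was -0.75 (adjusted p = 7.21e-08, and adjusted p = 0.0737 with an estimated correlation). Of 24 gluconeogenic and glyoxylate genes 14 fell, such as CRC1 (-2.80 ± 0.121) and MLS1 (-2.48 ± 0.113), and 3 rose (14 and 3 when adjusted over the list alone). The median was -0.87 (adjusted p = 2.53e-06, and adjusted p = 0.239 with an estimated correlation). Genes of mitosis had a median of -0.39, with 20 of 35 lower, such as CHS2 (-1.44 ± 0.183), and 2 higher (20 and 2 when adjusted over the list alone, adjusted p = 5.73e-05, and adjusted p = 0.217 with an estimated correlation). Thiamine and vitamin B6 genes had a median of -0.32, with 12 of 24 lower, such as THI4 (-2.27 ± 0.11), and 1 higher (12 and 1 when adjusted over the list alone, adjusted p = 0.000339, and adjusted p = 0.0816 with an estimated correlation). Among 39 regulators of glucose repression, PKA and TOR 15 fell, such as CAT8 (-1.90 ± 0.178) and ADR1 (-1.79 ± 0.161), and 3 rose (15 and 3 when adjusted over the list alone). The median was -0.19 (adjusted p = 0.000358, and adjusted p = 0.25 with an estimated correlation). Mitochondrial ribosome genes had a median of -0.19, with 16 of 66 lower (16 when adjusted over the list alone, adjusted p = 0.00267, and adjusted p = 0.606 with an estimated correlation), and the call was lost without wild-type replicate 2 (-0.13, adjusted p = 0.122). Heat shock proteins and chaperones had a median of -0.12, with 11 of 30 lower, such as HSP30 (-2.98 ± 0.123), and 4 higher (11 and 4 when adjusted over the list alone, adjusted p = 0.0131, and adjusted p = 0.159 with an estimated correlation).

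Camera called 7 lists with medians that were higher in fhf3 both with and without normalization, and 3 of the calls held with an estimated correlation. Of 79 ribosome biogenesis genes 63 rose, such as ARX1 (1.26 ± 0.117) and YTM1 (1.14 ± 0.132), and 66 when adjusted over the list alone, with a median of 0.57 (adjusted p = 1.16e-12, and adjusted p = 0.0201 with an estimated correlation). Of 61 amino acid biosynthesis genes 46 rose, such as TRP3 (1.22 ± 0.128) and GDH1 (1.15 ± 0.149), and 49 when adjusted over the list alone, with a median of 0.57 (adjusted p = 4.11e-10, and adjusted p = 0.0201 with an estimated correlation). Of 27 genes of RNA polymerases I and III 22 rose, such as RPC17 (1.33 ± 0.127), and 24 when adjusted over the list alone, with a median of 0.49 (adjusted p = 5.78e-06, and adjusted p = 0.0184 with an estimated correlation). Of 131 cytosolic ribosomal protein genes 36 rose and 95 did not pass (20 rose when adjusted over the list alone), with a median of 0.32 (adjusted p = 0.000105, and adjusted p = 0.688 with an estimated correlation). Of 33 sulphur assimilation genes 19 rose, such as MET14 (YKL001C; 1.82 ± 0.171) and MET16 (1.24 ± 0.108), and 5 fell (19 and 5 when adjusted over the list alone). The median was 0.37 (adjusted p = 0.00367, and adjusted p = 0.195 with an estimated correlation). Purine and one-carbon genes had a median of 0.47, with 19 of 24 higher, such as IMD2 (1.33 ± 0.13) and SHM2 (1.30 ± 0.137), and 19 when adjusted over the list alone (adjusted p = 5.73e-05, and adjusted p = 0.173 with an estimated correlation). COS genes had a median of 0.48, with 8 of 11 higher, such as COS8 (1.27 ± 0.151), and 9 when adjusted over the list alone (adjusted p = 0.00164, and adjusted p = 0.0925 with an estimated correlation). Without normalization between arrays the rises were smaller, such as 0.84 in ARX1, 0.69 in YTM1, 0.77 in TRP3, 0.87 in RPC17, 0.86 in IMD2 and 0.78 in COS8. The medians were then 0.19 for ribosome biogenesis, 0.26 for amino acid, 0.10 for RNA polymerase, 0.02 for ribosomal protein, 0.08 for sulphur, 0.16 for purine and 0.18 for COS genes.

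A last group of lists rose in fhf3 relative to the median of all genes. Translation factors and tRNA synthetases had a median of 0.32, with 21 of 45 higher (21 when adjusted over the list alone, adjusted p = 0.000529, and adjusted p = 0.182 with an estimated correlation). Genes of the unfolded protein response and secretion had a median of 0.29, with 17 of 38 higher (17 when adjusted over the list alone, adjusted p = 0.0036, and adjusted p = 0.275 with an estimated correlation). Hypoxic genes had a median of 0.30, with 10 of 26 higher, such as the sterol importer AUS1 (1.52 ± 0.12), and 2 lower (10 and 2 when adjusted over the list alone, adjusted p = 0.0426, and adjusted p = 0.118 with an estimated correlation). The hypoxic call was lost without fhf3 replicate 3 (0.23, adjusted p = 0.0708) or wild-type replicate 1 (0.20, adjusted p = 0.0529). Without normalization between arrays the median of all genes in fhf3 was -0.28, and these 3 list medians were -0.03, -0.06 and -0.05, above that median but below 0. The mating-type genes STE2 (YFL026W; -0.48 ± 0.111, adjusted p = 0.00229) and STE3 (YKL178C; 0.66 ± 0.122, adjusted p = 0.00043) moved apart in fhf3, but without normalization the STE3 call was lost (0.33) and STE2 differed by -1.03. In fhf1 and fhf2 STE2 (-0.09 and 0.14) and STE3 (0.11 and 0.34) did not pass, and neither did FLO11 in fhf1 (-0.29, adjusted p = 0.148), while FLO11 fell in fhf3 (-0.59 ± 0.131, adjusted p = 0.00161).

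Over all genes, limma called 1557 higher and 1206 lower in fhf3, of which 147 and 305 differed at least 2-fold. Of 48 lists camera called 23, of which 10 rose, and 8 calls held with an estimated correlation (36 by fry). Those 8 were general stress, ribosome biogenesis, peroxisome, amino acid biosynthesis, tricarboxylic acid cycle, RNA polymerases I and III, oxidative stress and autophagy. The unnormalized values gave 114 higher and 1317 lower genes, so the share of higher genes moved from 56.4% to 7.97%. The medians of lists that fell were then larger in size, such as -1.83 for general stress, -0.96 for respiratory, -0.67 for oxidative stress, -0.72 for autophagy and -0.56 for mitochondrial ribosome genes. Those of mitosis (-0.83), thiamine (-0.79) and heat shock genes (-0.40) and of regulators of glucose repression, PKA and TOR (-0.59) were larger too.

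**Figure D2:**
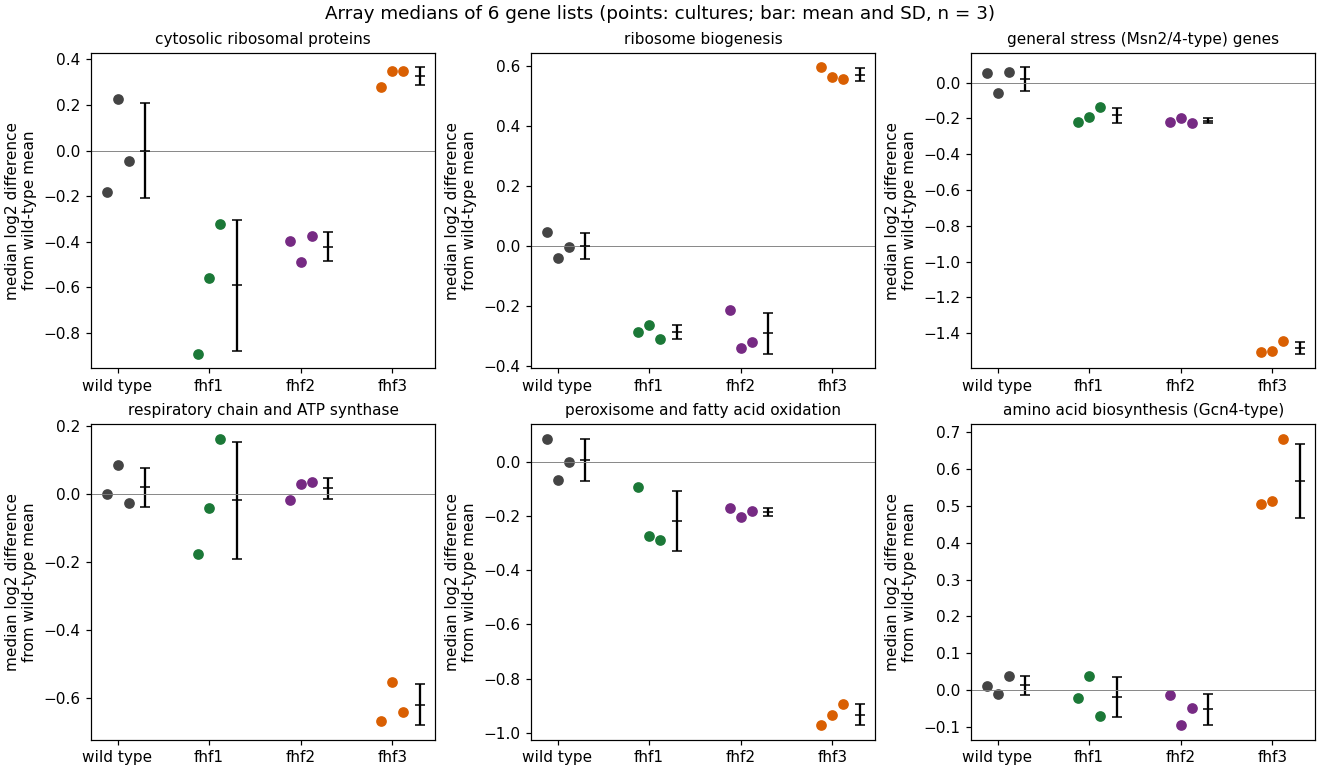
Median log2 difference from the wild-type mean of 6 gene lists in each of the 12 quantile-normalized arrays, with 1 point per array and a bar at the mean and SD (n = 3). Ribosomal protein medians were -0.89, -0.56 and -0.32 in fhf1 and 0.28, 0.35 and 0.35 in fhf3, and general stress medians lay between -1.51 and -1.44 in fhf3.

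The comparison of fhf1 with fhf2 asked which transcripts separate the pair of mutants that resembled each other most. The transporter HXT13 (1.70 ± 0.122, adjusted p = 2.14e-06), the proline permease PUT4 (YOR348C; 1.70 ± 0.259, adjusted p = 0.00206) and the glycerol symporter STL1 (YDR536W; 1.42 ± 0.186, adjusted p = 0.000607) were higher in fhf1. The G1 cyclin CLN2 (YPL256C; -1.13 ± 0.188, adjusted p = 0.00391), FUS2 (-1.08 ± 0.104, adjusted p = 6.97e-05) and HXT3 (-1.05 ± 0.128, adjusted p = 0.000491) were lower in fhf1. Thiamine and vitamin B6 genes had a median of 0.19, with 3 of 24 higher in fhf1 (5 when adjusted over the list alone, adjusted p = 5.15e-06, and adjusted p = 0.171 with an estimated correlation). Genes of G1/S and DNA replication had a median of -0.15, with 3 of 51 lower (11 when adjusted over the list alone, adjusted p = 5.15e-06, and adjusted p = 0.493 with an estimated correlation). Pheromone response genes had a median of -0.14, with 3 of 29 lower (6 lower and 1 higher when adjusted over the list alone, adjusted p = 0.000623, and adjusted p = 0.197 with an estimated correlation). The alpha-specific genes had a median of -0.24, with 1 of 7 lower (3 when adjusted over the list alone, adjusted p = 0.00021, and adjusted p = 0.284 with an estimated correlation), and nitrogen genes of 0.15, with 2 of 32 higher (3 when adjusted over the list alone, adjusted p = 0.00164, and adjusted p = 0.568 with an estimated correlation).

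In 6 further lists camera found a difference between fhf1 and fhf2. The medians of mitochondrial ribosome genes (-0.22, adjusted p = 6.91e-08, and adjusted p = 0.568 with an estimated correlation) and ribosomal protein genes (-0.16, adjusted p = 6.91e-08, and adjusted p = 0.801 with an estimated correlation) were lower in fhf1. Histones (-0.19, adjusted p = 0.0107, and adjusted p = 0.568 with an estimated correlation) and translation factors (-0.06, adjusted p = 0.0292, and adjusted p = 0.568 with an estimated correlation) were also lower. Ergosterol genes (0.13, adjusted p = 0.00348, and adjusted p = 0.171 with an estimated correlation) and autophagy genes (0.14, adjusted p = 0.0224, and adjusted p = 0.197 with an estimated correlation) were higher. Without fhf1 replicate 1 the ribosomal protein median was -0.02 (adjusted p = 0.587) and the histone median -0.08 (adjusted p = 0.191). The autophagy call was lost without fhf1 replicate 3 (0.14, adjusted p = 0.0682) or fhf2 replicate 1 (0.09, adjusted p = 0.0863), and the translation call without the same arrays (0.239 and 0.3) and without normalization (0.183). Medians without normalization were 0.09 for nitrogen, 0.11 for thiamine, 0.08 for autophagy, -0.23 for G1/S and -0.10 for translation genes. Over all genes 45 were higher and 46 lower in fhf1 than in fhf2, of which 11 and 6 differed at least 2-fold, and the total of 91 became 48 and 40 without fhf2 replicates 1 and 3. Camera called 11 of 48 lists and, with an estimated correlation, 0 (5 at an unadjusted p under 0.05, and 5 by fry).

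The comparison of fhf1 with fhf3 gave large differences in both directions. HSP12 (4.95 ± 0.151, adjusted p = 3.07e-12), SIP18 (YMR175W; 4.21 ± 0.144, adjusted p = 9.03e-12) and the transaldolase NQM1 (YGR043C; 3.75 ± 0.113, adjusted p = 3.07e-12) were higher in fhf1. HXK2 (-2.96 ± 0.156, adjusted p = 1.26e-09), MET14 (-2.58 ± 0.171, adjusted p = 1.42e-08) and the IMP dehydrogenase IMD3 (YLR432W; -2.41 ± 0.127, adjusted p = 1.22e-09) were lower. General stress genes had a median of 1.13, with 27 of 32 higher and 1 lower (27 and 1 when adjusted over the list alone, adjusted p = 8.53e-14). Ribosome biogenesis genes had a median of -0.89, with 73 of 79 lower (75 when adjusted over the list alone, adjusted p = 1.4e-24), and amino acid biosynthesis genes of -0.52, with 42 of 61 lower and 1 higher (44 and 1 when adjusted over the list alone, adjusted p = 2.54e-11). Ribosomal protein genes had a median of -0.91, with 124 of 131 lower and 1 higher (125 and 1 when adjusted over the list alone, adjusted p = 2.63e-25, and adjusted p = 0.271 with an estimated correlation). Respiratory genes had a median of 0.61, with 35 of 40 higher (35 when adjusted over the list alone, adjusted p = 8.38e-11, and adjusted p = 0.0671 with an estimated correlation).

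Over all genes 1364 were higher and 1386 lower in fhf1 than in fhf3, of which 212 and 263 differed at least 2-fold. Of 48 lists camera called 22, and 10 held with an estimated correlation (33 by fry). These were the 8 that held in fhf3 against wild type, together with translation factors (-0.49, 35 of 45 lower, 38 when adjusted over the list alone, adjusted p = 2.36e-08) and thiamine genes (0.51, 17 of 24 higher, 19 when adjusted over the list alone, adjusted p = 9.64e-06). Leaving out fhf1 replicate 2 ended the call of heat shock proteins (0.25, adjusted p = 0.0314; 0.19 and 0.0621 without it), and leaving out fhf1 replicate 3 that of mitochondrial ribosome genes (0.26, adjusted p = 0.00296; 0.18 and 0.0639 without it). With an estimated correlation these had adjusted p = 0.215 and 0.643. Genes of aryl alcohol, ester and fusel metabolism differed as well, with a median of 0.29 and with 14 of 28 higher and 3 lower (14 and 4 when adjusted over the list alone, adjusted p = 0.0202, and adjusted p = 0.144 with an estimated correlation). The unnormalized values gave 1700 higher and 267 lower genes, the share of higher genes moved from 49.6% to 86.4%, and the median of all genes was 0.38. The medians of purine genes (-0.31) and of secretion genes (-0.27) were then 0.07 and 0.12, both under that median. Those of ribosomal protein (-0.55), ribosome biogenesis (-0.55), RNA polymerase (-0.24), amino acid (-0.15), translation (-0.12) and sulphur genes (-0.06) were nearer to 0. Those of respiratory (1.02), tricarboxylic acid (1.08), thiamine (0.89), aryl alcohol (0.69), heat shock (0.67) and mitochondrial ribosome genes (0.64) were farther from it.

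The comparison of fhf2 with fhf3 gave similar groups. HSP12 (4.86 ± 0.151, adjusted p = 4.11e-12), NQM1 (3.81 ± 0.113, adjusted p = 4.11e-12) and SIP18 (3.76 ± 0.144, adjusted p = 5.56e-11) were higher in fhf2, while PRM7 (-3.23 ± 0.281, adjusted p = 2.97e-07) and MET14 (-2.48 ± 0.171, adjusted p = 2.4e-08) were lower. General stress genes had a median of 1.02, with 27 of 32 higher and 1 lower (27 and 2 when adjusted over the list alone, adjusted p = 1.12e-13). Ribosome biogenesis genes had a median of -0.90, with 74 of 79 lower (76 when adjusted over the list alone, adjusted p = 7.47e-24). Ribosomal protein genes had a median of -0.71, with 114 of 131 lower (124 when adjusted over the list alone, adjusted p = 1.92e-19, and adjusted p = 0.369 with an estimated correlation). Mitochondrial ribosome genes had a median of 0.41, with 40 of 66 higher (45 when adjusted over the list alone, adjusted p = 2.79e-08, and adjusted p = 0.374 with an estimated correlation). Over all genes 1288 were higher and 1371 lower in fhf2, of which 227 and 210 differed at least 2-fold. Camera called 22 of 48 lists, and 6 held with an estimated correlation (34 by fry), which were general stress, ribosome biogenesis, RNA polymerases I and III, amino acid biosynthesis, peroxisome and tricarboxylic acid cycle.

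Some of the list calls between fhf2 and fhf3 were less firm. The a-specific genes had a median of 0.26, with 5 of 9 higher (5 when adjusted over the list alone, adjusted p = 0.0446, and adjusted p = 0.146 with an estimated correlation). That call was lost without fhf2 replicate 3 (adjusted p = 0.0604), fhf3 replicate 2 (0.0541) or fhf3 replicate 3 (0.0632). Against wild type the a-specific (-0.30, adjusted p = 0.103) and alpha-specific genes (0.35, adjusted p = 0.128) did not pass in fhf3. In unnormalized values 1862 genes were higher and 145 lower in fhf2, the share of higher genes moved from 48.4% to 92.8%, and the median of all genes was 0.42. The medians of translation factors (-0.36), purine genes (-0.36) and secretion genes (-0.21) were then 0.07, 0.04 and 0.22, all under that median. Those of ribosomal protein (-0.29), ribosome biogenesis (-0.44), amino acid (-0.19), RNA polymerase (-0.20) and sulphur genes (-0.19) were nearer to 0 than with it, and those of respiratory (1.12), mitochondrial ribosome (0.87) and a-specific genes (0.75) farther. The autophagy median (0.33, adjusted p = 0.0182) was then 0.75 with adjusted p = 0.0727, and had adjusted p = 0.0711 with an estimated correlation.

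The mean of the 3 mutants was also set against wild type. DAL3 (1.68 ± 0.195, adjusted p = 1.33e-05), PUT1 (1.58 ± 0.137, adjusted p = 5.06e-07), DAL7 (YIR031C; 1.33 ± 0.138, adjusted p = 3.36e-06) and DUR12 (1.30 ± 0.0942, adjusted p = 5.83e-08) were among the largest mean rises. SPG4 (-3.85 ± 0.114, adjusted p = 3.89e-12), AQY1 (-3.73 ± 0.177), YDL218W (-3.59 ± 0.113, adjusted p = 5.2e-12) and SPS100 (-3.04 ± 0.119) were among the largest mean falls. General stress genes had a mean-mutant median of -0.58, with 21 of 32 lower (24 lower and 1 higher when adjusted over the list alone, adjusted p = 1.46e-17, and adjusted p = 0.00519 with an estimated correlation). Peroxisomal genes had a median of -0.49, with 17 of 27 lower and 1 higher (20 and 2 when adjusted over the list alone, adjusted p = 6.16e-11, and adjusted p = 0.0419 with an estimated correlation). Genes under nitrogen catabolite repression had a median of 0.19, with 12 of 32 higher and 2 lower (12 and 2 when adjusted over the list alone, adjusted p = 0.00758, and adjusted p = 0.376 with an estimated correlation). COS genes had a median of 0.37, with 10 of 11 higher (11 when adjusted over the list alone, adjusted p = 2.29e-05, and adjusted p = 0.0633 with an estimated correlation). Seripauperins had a median of 0.45, with 12 of 21 higher and 1 lower (13 and 1 when adjusted over the list alone, adjusted p = 4.29e-05, and adjusted p = 0.37 with an estimated correlation). Over all genes 679 were higher and 602 lower in the mean of the mutants, of which 16 and 101 differed at least 2-fold. Camera called 18 of 48 lists, of which general stress and peroxisome held with an estimated correlation (28 by fry). The values without normalization gave 40 higher and 270 lower genes, so the share of higher genes moved from 53.0% to 12.9%.

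In all 3 mutants 72 genes rose and 112 fell, against 2.82 and 4.71 expected if the mutants were independent. The total of 184 became 40 without normalization between arrays. DAL3, PUT1, EFM6, DAL7, DUR12 and COS10 were among those that rose, and SPG4, AQY1, YDL218W, SDH9, SPS100 and SPG1 among those that fell. The DAL3 call in fhf2 (0.92, adjusted p = 0.0303) was lost without fhf2 replicate 1 or 2 (adjusted p = 0.108 and 0.144) or wild-type replicate 1 or 3 (0.0715 and 0.104). The DAL7 call in fhf2 (0.91) was lost without normalization (0.90, adjusted p = 0.0669). Since the 3 comparisons share the wild-type arrays, unchanged groups were simulated with a simulated wild type in common. These gave a mean of 0.1 and a highest count of 10 such genes over 100 draws. The observed wild-type arrays were not kept in the draws, which therefore do not show what those very arrays could add. The mutants fhf1 and fhf2 shared 99 higher and 196 lower genes (10.4 and 22.5 expected), with 2 genes in opposite directions (31.6 expected). Between fhf1 and fhf3 257 higher and 208 lower genes were shared (120 and 107 expected) and 145 were opposite (232 expected), among them HXK2 and IMD3. Between fhf2 and fhf3 89 higher and 146 lower genes were shared (36.4 and 52.9 expected) and 71 were opposite (96.5 expected). In the simulations the highest shared counts, higher and lower, were 15 and 8, 13 and 8, and 6 and 4 for these pairs.

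Fold changes of fhf1 and fhf2 were the ones most alike across genes, with r = 0.792, against 0.393 for fhf1 and fhf3 and 0.441 for fhf2 and fhf3. Simulated unchanged groups with a simulated wild type in common gave mean r of 0.529 (-0.287 to 0.947), 0.469 (-0.455 to 0.936) and 0.492 (-0.601 to 0.930) over the central 95% of 100 draws. The observed r all lay inside these ranges. The covariances were 0.0814, 0.0880 and 0.0829, the simulated ones 0.0125, 0.0104 and 0.0113, and the differences 0.0689, 0.0776 and 0.0716. Wild type has 3 arrays, too few to split into parts of 2 or more. Each mutant of a pair was therefore set against a different single wild-type array, a check chosen after the correlations were seen. Over the 6 choices r ran from 0.320 to 0.676, from 0.129 to 0.397 and from 0.176 to 0.405, with mean covariances of 0.0676, 0.0742 and 0.0691. Shared counts were not repeated in this way, so some of the excess of shared genes may come from the shared controls.

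**Figure D3:**
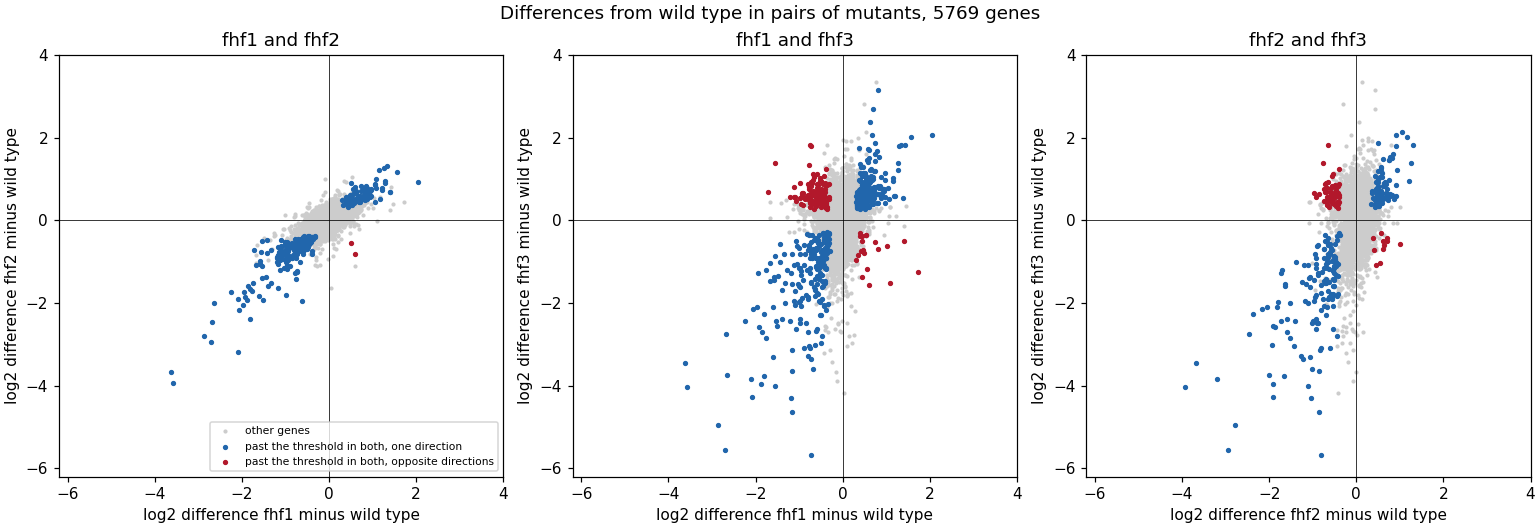
Log2 differences from wild type of each of 5769 genes in 1 mutant against another, with 1 panel per pair of mutants and 1 point per gene, blue where both mutants passed in 1 direction and red where they passed in opposite directions. The Pearson correlations across genes were 0.792 for fhf1 and fhf2, 0.393 for fhf1 and fhf3 and 0.441 for fhf2 and fhf3.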

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

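The tests of scaling in this part were chosen only after the result was seen, as were the interval asked of the growth state test and the setting without normalization, while the other tests were set before. What brought the results here is that fhf1, fhf2 or fhf3 moved in opposite directions from wild type and that limma's direct test between the mutants passed. This held for 10 medians of 6 lists and for 47 differences of 28 named genes. With groups of 3 no array was tested as an outlier.

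The median of ribosomal protein genes was lower in fhf1 and fhf2 than in wild type and higher in fhf3, while most members did not pass in fhf2 or fhf3. The medians of differences were -0.91 between fhf1 and fhf3 and -0.71 between fhf2 and fhf3. With an estimated correlation these calls were lost (adjusted p = 0.271 and 0.369), as were those of fhf1, fhf2 and fhf3 against wild type (0.379, 0.338 and 0.688). Scaling between arrays is argued against for the falls in fhf1 and fhf2, whose medians were -0.31 or further from 0 under 4 scalings. For the rise in fhf3 scaling stays open, since its median was 0.0207 without normalization and 0.32 to 0.40 under the other scalings. Relative to the median of all genes it was 0.25 to 0.31 under all 4, but a constant shift of an array cannot move that measure. A single array as the whole cause is argued against too, since at least 0.685 of the median was kept in each mutant with any array left out, the smallest share being in fhf3 without wild-type replicate 1 (0.22). A growth state that also varies between cultures of 1 strain may contribute, and it stays open, since ribosomal and general stress medians gave r = -0.0442 within strains. This lay above the bound of -0.2 set beforehand, but its interval, required only after r was seen, reached across the bound (12 arrays, 95% interval -0.688 to 0.639, exact permutation p = 0.887 over 1296 permutations, Spearman rho 0.028 with exact permutation p = 0.951, and r = 0.145 without the 2 arrays farthest out). A direct effect of each strain's mutations was not tested and is also open.

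Other groups that differed this way were ribosome biogenesis (-0.89 and -0.90 for fhf1 and fhf2, each minus fhf3), translation factors and tRNA synthetases (-0.49 and -0.36) and sulphur assimilation (-0.44 and -0.60). Mitochondrial ribosome genes (0.41) and genes of RNA polymerases I and III (-0.64) did so for fhf2 minus fhf3. With an estimated correlation the calls held for ribosome biogenesis (adjusted p = 0.00669 and 0.00689), for translation in fhf1 minus fhf3 (0.0423) and for RNA polymerases (0.00926). They were lost for sulphur assimilation (0.0735 and 0.0711), translation in fhf2 minus fhf3 (0.0711) and mitochondrial ribosome genes (0.374). Without normalization the translation median of fhf2 minus fhf3 was 0.07, and that of fhf3 minus wild type, 0.32 with normalization, was -0.03.

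Between fhf1 and fhf2 2 named genes had opposite directions, with fhf1-minus-fhf2 differences of 1.42 in STL1 and 1.06 in LYS9. For fhf1 minus fhf3 the differences were 2.98 in YBR072C-A, 1.91 in DIN7, 2.15 in STL1, 1.19 in GPD1, 0.70 in MRP1 and 1.26 in NDI1, which were higher in fhf1. Lower in fhf1 were HXK2 (-2.96), MET14 (-2.58), YFL051C (-2.52), IMD3 (-2.41), MET16 (-1.61), SAM4 (-1.67), HOM3 (-1.10) and TEF4 (-1.22). The ribosomal protein genes RPL22B (-1.76), RPL11A (-1.57) and RPS29A (-1.38) and the polymerase subunits RPA49 (-1.88), RPA43 (-1.33) and RPA34 (-1.71) were lower as well. The same held for the ribosome biogenesis genes HAS1 (-1.34), EMG1 (-1.56), UTP21 (-1.25), DBP2 (-1.09), NOP14 (-1.21) and UTP8 (-1.80). In fhf1 against wild type the limma call of HOM3 was lost without wild-type replicate 3 (adjusted p = 0.0551), and that of GPD1 on leaving out single arrays, as given above.

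For fhf2 minus fhf3, DIN7 (1.19), FUS2 (1.57) and MRP1 (0.85) were higher in fhf2. HXK2 (-2.16), MET14 (-2.48), MET16 (-1.65), IMD3 (-1.41), LYS9 (-1.63) and SAM4 (-1.19) were lower in fhf2. So were RPL22B (-1.48), RPL11A (-1.48), RPS29A (-1.16), RPA49 (-1.59), RPA43 (-1.11), HAS1 (-1.07), EMG1 (-1.25), DBP2 (-1.12), NOP14 (-1.12) and UTP8 (-1.65). Some limma calls of fhf2 against wild type behind these were lost on leaving out single arrays. That of MET14 was lost without fhf2 replicate 1 or 2 (adjusted p = 0.119 and 0.107) or wild-type replicate 2 or 3 (0.0936 and 0.0759). That of SAM4 was lost without fhf2 replicate 2 or 3 (0.139 and 0.109) or wild-type replicate 2 or 3 (0.102 and 0.088). Those of NOP14, RPL11A, RPL22B and RPA43 were also lost on leaving out single arrays.

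Without normalization all 47 differences kept opposite directions from wild type and 44 passed between the mutants, but in only 4 did both calls against wild type hold. The 3 that did not pass were HAS1 (-0.62, adjusted p = 0.0548), NOP14 (-0.62, adjusted p = 0.0547) and RPA43 (-0.62, adjusted p = 0.0532) for fhf2 minus fhf3, whose rises in fhf3 of 0.40, 0.58 and 0.57 were then 0.02, 0.10 and 0.10. In all, 10 differences moved over 1.5 times. Besides these 3 they were EMG1 (-0.80), SAM4 (-0.72), DBP2 (-0.67), RPS29A (-0.74) and MRP1 (1.30) for fhf2 minus fhf3, and HOM3 (-0.73) and MRP1 (1.12) for fhf1 minus fhf3.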

How the results depend on the processing

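No normalization, treat at 2-fold without it, the coding length correction, the filter of the highest 10% of genes and the use of different wild-type arrays were chosen after the data were seen, and the other settings before. Counts are given in the order fhf1, fhf2 and fhf3 against wild type, fhf1 against fhf2, fhf1 against fhf3 and fhf2 against fhf3, then the mean of the mutants, any strain difference and all 3 mutants. The main counts were 960, 388, 2763, 91, 2750, 2659, 1281, 3147 and 184. A log2 limit of 1 left 104, 54, 452, 17, 475, 437, 117, 497 and 34, since it requires a larger change. Treat at 1.2-fold gave 222, 94, 1319, 22, 1370 and 1295 genes, 325 for the mean and 63 in all 3. Without normalization 154, 59, 1431 and 18 genes passed in the first 4 comparisons, 310 for the mean, 1816 for any strain difference and 40 in all 3. Treat at 2-fold without normalization gave 11, 9, 169, 0, 110 and 108, with 36 for the mean and 8 in all 3, and the 0 stood beside 2 genes at an unadjusted p under 0.05 by treat and 91 by the main test. Array weights gave 1742 genes in fhf1, 814 in fhf2, 882 between fhf1 and fhf2 and 357 in all 3. A fit of only the compared groups gave 488 in fhf1, of which 486 were among the 960. The length correction gave 619 in fhf2 and 195 between fhf1 and fhf2. Leaving out the lowest 25% of genes, which tests fewer genes, gave 243, 54 and 102 in fhf2, between fhf1 and fhf2 and in all 3, and correlations of fold changes of 0.757, 0.327 and 0.369. The correlations of fhf1 and fhf2 with fhf3 were 0.347 and 0.416 with median centring and also without normalization, and cyclic loess gave 0.352 for fhf1 and fhf3. Of the called lists 0, 0, 8, 0, 10 and 6 passed with an estimated correlation, where the counts of 0 stood beside 5, 9 and 5 at an unadjusted p under 0.05 and 20, 15 and 5 by fry. Fry called 36 lists in fhf3, 5 between fhf1 and fhf2 and 34 between fhf2 and fhf3, and median centring called 17 between fhf1 and fhf2. On leaving out each array the counts ran from 647 to 946, 213 to 506, 2375 to 2898, 40 to 106, 2381 to 2852, 2233 to 2783, 889 to 1394, 2719 to 3337 and 132 to 221. The lists ran from 13 to 15, 13 to 15, 22 to 25, 9 to 15, 21 to 22 and 21 to 22, and the correlations from 0.733 to 0.819, 0.346 to 0.447 and 0.420 to 0.495. The count in fhf2 was 246, 213 and 224 without fhf2 replicates 1, 2 and 3 and 225 without wild-type replicate 3, and that between fhf1 and fhf2 was 48 and 40 without fhf2 replicates 1 and 3. Residuals of arrays with the same replicate number correlated at -0.264 to 0.492 (mean 0.141, 11 of 18 pairs above 0.1), against a mean of -0.0715 and 9 of 36 pairs for different numbers, and 7 of 12 arrays correlated best with their own number. Residuals cancel over the arrays of a strain, so the mean of -0.0715 follows from the 0.141 and adds no evidence. The values for the same number lean toward shared conditions, but not every pair lay above 0.1. No label names a batch, so the numbers were not treated as pairs. A replicate block gave 1130, 514, 2947, 136, 2952, 2830, 1488, 3453 and 222, and each of the 107 called list medians kept its call. Among 379 values of named genes, 89 calls were lost without normalization and 289 kept their side of the threshold, and ADH2 in fhf3 changed direction (-0.13, also with treat). Leaving out arrays was counted once per value and array left out. In 135 of these cases the call was lost, in 1 it was gained, and in 4412 the side of the threshold was kept. Counted per call, 34 of 321 named calls were lost with some array left out. Of 107 called list medians 83 lost the call with an estimated correlation and 24 kept it. Without normalization the spread of array medians within a strain, such as 12.838, 12.151 and 12.845 in fhf1, enters the error of each gene. A lost call then need not mean a smaller difference, as with GPD1 in fhf1 (0.36 with normalization and 0.52 without). Except where a reason is given, the cause was not tested. Signals near the top of the range may be compressed, as 18 of 24 glycolytic genes lay above the 90th percentile, which limits what small differences in them show. The planned quantile normalization was the main setting itself, and a fit of the other deposited table was not run, because that table holds no values per array.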

Other observations

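Of the tests in this part, those of chromosomes and of scaling, the coding length correction and treat at 2-fold without normalization were chosen only after the result was seen.

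Stress, respiratory and storage carbohydrate genes were lower in fhf3, where with an estimated correlation the general stress call held (adjusted p = 0.00632) and the respiratory (0.0636) and storage carbohydrate (0.0737) calls were lost. Scaling between arrays is argued against, since general stress, respiratory and storage carbohydrate medians kept at least 0.884 of their size under 3 other scalings, the smallest share being that of storage carbohydrate genes with median centring (-0.66 against -0.75). A bias by gene length is argued against for general stress genes, since a correction for coding length kept 0.990 of their median (-1.46 before and -1.44 after). A gain or loss of a whole chromosome is argued against, since no median of the 16 nuclear chromosomes lay more than 0.0979 from that of all genes (chromosome I). A biological difference between the strains, or a different stage of fermentation at day 2, was not tested and stays open.

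PRM7, YDL038C and BSC1, which lie next to each other on the same strand, were the genes with the largest rises in fhf3. In assembly R64 YDL038C is part of PRM7, so that 1 of the 3 pairs overlaps, and signal shared between overlapping genes could explain that pair, while BSC1 overlaps neither. Log2 differences in fhf3 correlated at 0.745 across 60 overlapping pairs of genes and at 0.162 across 5686 adjacent pairs, a difference of 0.583 (95% interval 0.411 to 0.696 over 1000 bootstrap draws). Over the 12 arrays, deviations from strain means of the 3 genes correlated at 0.469 for the lowest pair and 0.875 for the highest. One transcribed region across them cannot be told apart from separate rises, since correlated deviations can come with either.

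Other groupings of the arrays were tried for each count. For the 6 comparisons of 3 arrays against 3 the 10 splits are too few for a share under 0.05, and 1 of 10, the real one, gave the highest count in each. The real counts and the highest of the other splits were 960 and 1 for fhf1 against wild type, 388 and 0 for fhf2, and 2763 and 0 for fhf3. They were 91 and 1 for fhf1 against fhf2, 2750 and 0 for fhf1 against fhf3, and 2659 and 0 for fhf2 against fhf3. For the mean of the mutants, for any strain difference and for all 3 mutants, 1 of 100 groupings, the real one, gave as many genes. The real counts were 1281, 3147 and 184, and the highest others 365, 2130 and 0. For any strain difference these values argue against a chance assignment of the arrays to the 4 strains. For the mean of the mutants and for all 3 mutants they cannot decide. The other groupings mixed the distant fhf3 arrays with those of other strains, which widens the spread within groups.

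The authors' deposited table called 11 genes in fhf1, 9 in fhf2 and 170 in fhf3, all lower except 5 in fhf3. Treat at 2-fold without normalization called 11, 9 and 169, all of which the authors had called. The remaining gene, HPA2, has no array values in the table analysed here, and the authors' table gives it a log2 difference of -3.52 with adjusted p = 2.76e-15 in fhf3. In all, 8 genes of that table had no array values here.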
